A study of Cereibacter sphaeroides with 9 samples.

How the data were processed

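Transcript levels of the purple photosynthetic bacterium Cereibacter (Rhodobacter) sphaeroides were measured on 9 Affymetrix arrays, 3 for each of 3 strains named 16, HR and PHC. Per the labels, cells were grown photoheterotrophically, in light on an organic carbon source, at 30 °C in Ormerod's medium with malate, and the 3 arrays of a strain are biological replicates. The labels name the strains and give no genotype, so values are reported by strain name. Groups and replicate numbers were taken from the sample titles.

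The authors deposited 1 table of processed intensity values, in whole numbers between 17 and 24774 on a linear scale, for 5355 numbered probe sets. Per the submitters' processing notes the tools were MAS5 and RMA. Their versions and roles are not given in the sources used here, so which of them made the deposited intensities, and with what background correction, stays unknown. Array medians lay between 140 and 152, so the arrays had been brought to a common scale before deposit. Detection calls were not used here, so a fold against a dim value depends on the background left in it, and the number of arrays limits the precision.

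Genes were named only from the platform's annotation as held by GEO, which can be old. It gave 1 gene symbol for 539 of the tested probe sets, several symbols for 0, and none for 4813, which are unnamed here. The named probe sets stand for 514 genes. No Gene ID matched the RefSeq gene table of assembly ASM332471v1 (0 matches), while 497 of 497 symbols were found there as a symbol or synonym. A symbol carried by 2 Gene IDs is printed with its Gene ID. The 3 probe sets for thrC, a spike-in control gene of another bacterium, were left out, which leaves 5352. Other control probe sets cannot be told apart by number and stay in. The genes cbbL, cbbS and cbbM, which were to be named in any case, are not analysed here by name, and the locus ranges set for some lists were not used.

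Values were tested as log2(value + 1), with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). A linear model with 1 mean per strain was fitted to all 9 arrays, followed by empirical Bayes moderation. Tests were two-sided, with Benjamini-Hochberg adjustment over the 5352 probe sets of a comparison and a threshold of 0.05. A further count asked for a change of at least 2-fold. Fold changes are on the log2(value + 1) scale, which understates the change of dim genes. SDs are of the deposited intensities over the 3 arrays of a strain, and SEs are of the log2 change. A probe set was called strain-specific when it passed against both other strains with the same sign.

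Before the data were examined, 18 gene lists were fixed by symbol. Of these, 13 had at least 3 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 39 tests of lists and comparisons. Camera with an estimated correlation and fry were run beside it. Each gene entered a list through its brightest probe set. Counts of members that rose or fell use the adjustment over all probe sets, and those "adjusted over the list alone" use only the list's members. The nifA, nifK and glnA genes stand in the series title, so the lists that hold them were not chosen blind to the study.

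The genes to be named were also fixed by rule before the data were examined. They are glnA, nifA, nifK, nifH, nifD and cbbR, the 10 largest rises and the 10 largest falls per comparison among probe sets that passed with no overlap between replicates, and up to 4 members per list by adjusted p. The rule of 10 was applied to probe sets with a symbol, and at most 2 unnamed probe sets that rose and 2 that fell are given per comparison. A few further list members are named where a count rests on them, chosen after their values were seen. Some genes that the rule selects, such as metF and wcaG, are not described in the results.

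The procedure was tested on simulated data built from the spread of these arrays, over 5352 probe sets. For strain PHC against strain 16, 58% of 1.25-fold changes, 88% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes were recovered, with 10 calls among unchanged probe sets. For strain PHC against strain HR the recovered shares were 56%, 94%, 98% and 100%, with 6 such calls. For strain 16 against strain HR, where no change was put in, there were 0 calls. Only 50 probe sets were changed at each fold, while 44.6% to 46.4% changed in a comparison of the data. A probe set also had the same simulated spread on all arrays. These shares and calls therefore give no rate of recovery or false calls for the data. In a simulated list test the ribosomal protein list alone was shifted, by 0.5 on the log2 scale in strain PHC. It was called in both comparisons of that strain, and 0 of 37 unshifted tests were called. Probe sets were simulated independently, so this gives no rate of false calls for lists whose genes vary together.

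The alternatives were quantile normalization, median centring, leaving out the dimmest 25% of probe sets, a pseudocount of 16, a fit of only the 6 arrays compared, moderation with an intensity trend and robust prior, array weights, the replicate number as a block, each array left out in turn, and an adjusted p threshold of 0.01.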

Results

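The series set 3 strains of C. sphaeroides side by side in matching photoheterotrophic growth to find strain-specific expression, and its title concerns mutations in GlnA, NifA and NifK that allow photosynthetic growth without CO2 fixation. Each strain was measured on 3 arrays. Median intensities were 144.5, 144.5 and 145 for strain 16, 142, 140 and 143.5 for strain HR, and 152, 149 and 147 for strain PHC. Pearson's r between log2 values, across probe sets within pairs of arrays, was 0.991 to 0.998 within a strain and 0.937 to 0.972 between strains. Probe sets are not independent replicates. The first principal component held 62.9% of the variance and the second 29.2%. Strain HR replicate 3 stood apart, with an SD of 0.177 on the log2 scale around its strain's means against 0.0698 to 0.11 for the other arrays. No preparation batch is named in the labels used here, so a batch that followed the strains could not be told apart from them.

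Strain PHC was first compared with strain 16. The genes of nitrogen fixation were far higher in strain PHC. Intensity of nifH, which encodes the iron protein of nitrogenase, was 12682 ± 825 (SD, n = 3) in strain PHC and 62.0 ± 4.58 (SD, n = 3) in strain 16, a 201-fold difference. For nifD and nifK, the subunit genes of the molybdenum-iron protein, the means were 7884 ± 249 against 52.0 ± 3.61 and 6547 ± 268 against 32.3 ± 1.15 (SD, n = 3 each). The activator gene nifA was 2.39-fold higher, at 501 ± 33.8 against 209 ± 2.65. Glutamine synthetase, encoded by glnA, was at 432 ± 46.9 in strain PHC and 363 ± 36.5 in strain 16, and that difference did not pass (adjusted p = 0.0824).

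All 12 measured genes of the nitrogenase list rose, each by at least 2-fold, and 12 rose when adjusted over the list alone. The list holds nifA and nifK from the series title. Their log2 changes ran from 1.26 for nifA to 7.65 for nifH, and nifB, nifX and nifS, which act in cofactor and cluster assembly, rose by 5.25, 4.94 and 4.66. The list's shift had a camera adjusted p of 7.72e-17, and an adjusted p = 0.178 with an estimated correlation. In strain 16, 10.3% of probe sets were dimmer than nifK and 31.2% were dimmer than nifH, so these folds rest on values in the dim part of the range.

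Protein quality control genes were also higher in strain PHC. Of 9 chaperone and protease genes 8 rose, 0 fell and 1 did not pass, with the same 8 when adjusted over the list alone. The chaperone gene dnaK reached 2028 ± 153 against 914 ± 68.6, its partner dnaJ rose by 0.96 on the log2 scale, and groEL Gene ID 3719842 by 0.78. The list's camera adjusted p was 0.000466, and its adjusted p = 0.332 with an estimated correlation. Of 45 ribosomal protein genes 20 fell, 3 rose and 22 did not pass (20 and 3 adjusted over the list alone). Examples are rpsT, rpmH and rpmC, at log2 changes of -1.42, -1.38 and -1.22. The list's shift did not pass in the full set (adjusted p = 0.0529, or 0.672 with an estimated correlation) and passed without any 1 of 5 arrays. The adjusted p was 0.0438 and 0.0234 without strain 16 replicate 2 or 3, 0.0491 and 0.0289 without strain HR replicate 2 or 3, and 0.0296 without strain PHC replicate 3.

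Among single genes, the largest named fall was that of moaA Gene ID 3721636, a gene of molybdenum cofactor synthesis, at 38.0 ± 1.73 in strain PHC and 1716 ± 111 in strain 16. The serine acetyltransferase gene cysE Gene ID 3721647 fell by 2.49 on the log2 scale. The biotin carboxyl carrier gene accB and the histidine synthesis gene hisA fell by 1.27 and 1.32. The regulator gene of CO2 fixation, cbbR, rose 5.48-fold to 1532 ± 42.7, while cbbX, encoding an activase of RubisCO, fell from 2124 ± 97.7 to 1473 ± 21.5. Respiratory genes ccoO and ccoP, for subunits of the cbb3 oxidase, fell by 0.70 and 0.69. The paired regulator genes dorR and dorS, which act on DMSO reductase expression, fell by 0.63 and 0.26. Genes ihfB and appA, of the list of redox and photosynthesis regulators, fell by 1.03 and 0.78, appA with all 5 probe sets passing. On that list 3 of 12 rose, nifA and cbbR among them, and 3 fell, the same adjusted over the list alone. Its shift did not pass (camera adjusted p = 0.652). The polyhydroxybutyrate synthase gene phaC rose by 0.91. The gene exbD, of an energy-transducing membrane complex, rose by 1.43 and the iron-sulfur assembly gene SufC by 0.83, within a metal and iron-sulfur list where 5 of 10 rose and 1 fell (7 and 1 adjusted over the list alone). That list's shift did not pass (camera adjusted p = 0.083) and passed without strain HR replicate 3, the array that stood apart (adjusted p = 0.0289). Bacteriochlorophyll and carotenoid genes had 6 rises and 7 falls among 23, the same adjusted over the list alone (camera adjusted p = 0.931). Among them hemF and crtB fell by 0.83 and 0.41, and hemN rose by 0.40.

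Over all 5352 probe sets, 2387 changed between strain PHC and strain 16, of which 1109 rose and 1278 fell. The share of rises was 46.5%, and 38.8% after median centring. At least 2-fold changes numbered 374, with 220 up and 154 down, and 262 named genes changed. Probe sets 4140 and 4144 were the unnamed ones with the largest rises, at log2 changes of 6.34 and 6.06. Unnamed probe sets 3997 and 3998 fell by 6.95 and 5.43.

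**Figure D1:**
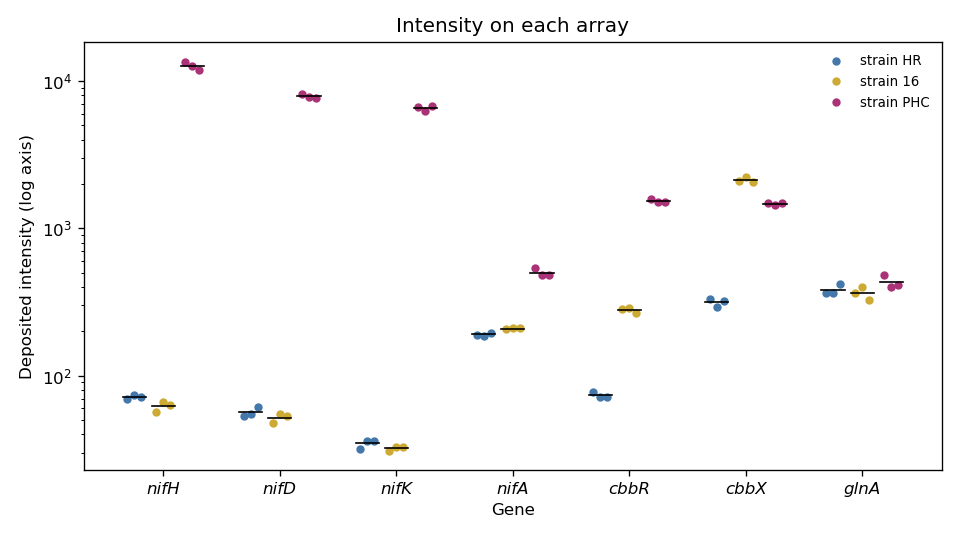
Deposited intensity (log axis) of 7 genes on each of the 9 arrays, coloured by strain, with 1 point per array and a black line at the strain mean. The nifH points of strain PHC lie between 11858 and 13507 and those of the other strains between 57 and 74, while the 3 strains overlap for glnA.

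Strain PHC was next compared with strain HR. The nitrogenase genes again stood highest, with nifH at 71.7 ± 2.52 in strain HR, 174-fold under strain PHC, and nifK at 34.7 ± 2.31, 184-fold under it, folds that again rest on dim values. Activator gene nifA was at 191 ± 4.73 in strain HR and rose by 1.39 on the log2 scale. The regulator gene cbbR rose 20.5-fold from 73.7 ± 2.89, and cbbX rose 4.66-fold from 315 ± 20.1. Levels of glnA, at 384 ± 31.5 in strain HR, did not pass (adjusted p = 0.211).

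All 12 nitrogenase list genes rose by at least 2-fold, and 12 rose adjusted over the list alone, with a camera adjusted p of 1.97e-17 and an adjusted p = 0.178 with an estimated correlation. Ribosomal protein genes were lower in strain PHC almost throughout. Of 45 genes 44 fell, 0 rose and 1, rpsU, did not pass, with 44 falls adjusted over the list alone, and the list's median log2 change was -0.52. Large falls were those of rpmC, from 5568 ± 1316 to 1882 ± 25.8, and rpsI, from 2459 ± 533 to 1024 ± 52.4. The list had a camera adjusted p of 1.09e-12, and an adjusted p = 0.269 with an estimated correlation. Without strain HR replicate 3, the array that stood apart, its median was -0.56 and rpsU passed as well (log2 change -0.76, adjusted p = 0.0115), as it did with array weights (0.0241).

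Genes of the citric acid cycle included sucC and sucD, for succinyl-CoA synthetase, which fell by 1.54 and 0.89, and malate dehydrogenase gene mdh, which fell by 0.54. Of 8 such genes 5 fell, 1 (citrate synthase gene gltA) rose and 2 did not pass, the same adjusted over the list alone. The list's camera adjusted p of 0.0493 became 0.071 without strain HR replicate 3, 0.0583, 0.0541 and 0.0549 without strain PHC replicate 1, 2 or 3, 0.0847 after median centring, 0.0521 after quantile normalization, 0.0675 without the dimmest probe sets and 0.0547 with the replicate number as a block, and it was an adjusted p = 0.332 with an estimated correlation. The fatty acid synthesis gene fabA fell by 1.19, the translation initiation gene InfC by 1.16, the phosphate response gene phoB by 1.09 and surE by 1.08.

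Between strains PHC and HR, the photopigment regulator genes ppaA and ppsR were higher in strain PHC by 1.83 and 0.84, the latter with all 5 of its probe sets passing. The regulator gene appA did not pass at its brightest probe set (log2 change of -0.13), and 1 of its 5 probe sets passed as a fall. Of 12 genes on the regulator list, which shares nifA and cbbR with other lists, 7 rose, 1 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00287, and adjusted p = 0.332 with an estimated correlation). Bacteriochlorophyll and carotenoid genes, listed together with hem genes, showed 12 rises and 4 falls among 23 (12 and 6 adjusted over the list alone). Genes bchF, bchO and crtA rose by 0.87, 0.75 and 0.34. The 4 falls were those of crtC, crtD, hemE and hemF, by 0.32, 0.20, 0.25 and 0.42. That list's camera adjusted p of 0.0463 rose to 0.059 and 0.0691 without strain PHC replicate 1 or 3, and to 0.0991 without the dimmest probe sets, and it was an adjusted p = 0.672 with an estimated correlation. Protease genes clpA, ftsH and lon rose by 0.87, 0.42 and 0.46, among 5 rises, 0 falls and 4 not passing for chaperones and proteases (5 adjusted over the list alone, camera adjusted p = 0.00794, adjusted p = 0.399 with an estimated correlation). The molybdate-binding protein gene modA rose by 1.13 and exbD by 1.09, among 5 rises of 10 in the metal and iron-sulfur list (5 adjusted over the list alone). Its camera adjusted p of 0.0474 became 0.0583 and 0.0691 without strain PHC replicate 1 or 3, 0.0863 without the dimmest probe sets, and adjusted p = 0.626 with an estimated correlation.

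In total 2483 probe sets changed between strain PHC and strain HR, 1149 up and 1334 down, and 297 named genes changed. The share of rises among them was 46.3%, and 31.7% after median centring. Changes of at least 2-fold numbered 317, with 207 up and 110 down. Probe sets 4140 and 4144 again led the unnamed rises, at 6.31 and 5.94 on the log2 scale. Unnamed probe sets 4222 and 2182 fell, with log2 changes of -5.15 and -4.11, to 40.7 ± 1.15 and 53.7 ± 1.53 in strain PHC.

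Strain 16 was finally compared with strain HR. Here the nitrogenase genes lay low in both strains, with nifK at 32.3 and 34.7 (adjusted p = 0.212) and nifD at 52.0 and 56.3 (adjusted p = 0.209). Of the 12 list genes 1, rpoN, rose, 2, nifH and nifS, fell by 0.21 and 0.34, and 9 did not pass (1 rise and 1 fall adjusted over the list alone, camera adjusted p = 0.555). Among the 9 was nifA, at a log2 change of 0.13 (adjusted p = 0.0677, and 0.0225 to 0.538 over the alternatives), which passed as a rise with array weights (0.0225) and in the fit of 6 arrays (0.0401). The nifH call (adjusted p = 0.0374) was lost without strain 16 replicate 1 or 3 (0.112 and 0.0625), without strain HR replicate 2 or 3 (0.109 and 0.0722), and under 6 other alternatives (0.0514 to 0.0978), and the nifS call after quantile normalization (0.0518). Molybdenum cofactor gene moaA Gene ID 3721636 rose to 1716 ± 111 in strain 16 from a dim 38.7 ± 2.08 in strain HR, and cbbX rose 6.72-fold. The cbbR gene rose 3.75-fold, and glnA did not pass (adjusted p = 0.558).

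Ribosomal protein genes were lower in strain 16 than in strain HR, with 33 of 45 lower, 1 (rpsU) higher and 11 not passing (35 and 1 adjusted over the list alone). Examples are rplX, at 3796 ± 260 against 6821 ± 499, and rplE, at 3200 ± 126 against 5665 ± 313. The rise of rpsU was lost without any 1 of 5 arrays, at adjusted p = 0.0806, 0.0931 and 0.123 without strain 16 replicate 1, 2 or 3 and 0.0533 and 0.0602 without strain HR replicate 2 or 3, the last with a log2 change of 0.50, and under 4 other alternatives (0.0503 to 0.085). The camera adjusted p was 2.68e-08, and the adjusted p = 0.332 with an estimated correlation. The elongation factor gene tsf fell by 0.88. Chaperone genes dnaK, dnaJ and groEL Gene ID 3719842 fell by 1.02, 0.76 and 0.67, within a list of 4 falls, 1 rise and 4 not passing, the same adjusted over the list alone, whose shift did not pass (camera adjusted p = 0.399).

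Regulator genes ppaA, ppsR and appA, which act on photosynthesis genes, rose in strain 16 by 1.03, 0.71 and 0.65. On that list 8 of 12 rose, 0 fell and 4 did not pass (9 and 0 adjusted over the list alone), with a camera adjusted p of 7.55e-05 and an adjusted p = 0.269 with an estimated correlation. Pigment synthesis genes showed 10 rises and 1 fall among 23, the same adjusted over the list alone, with bchY at 1796 ± 122 against 1236 ± 67.3 (camera adjusted p = 0.00532, and adjusted p = 0.628 with an estimated correlation). The sulfate transport genes cysT and cysW fell by 1.61 and 1.32, the carbamoyl phosphate synthetase gene carB by 1.41, and phaC by 1.05. The glutamate synthase gene gltB fell from 1266 ± 32 to 681 ± 61.7, and leuD, of leucine synthesis, fell by 0.95. The methionine sulfoxide reductase gene msrA rose by 1.51 and modA by 1.14.

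Hydrogenase maturation genes hypA, hypB and hypD rose in strain 16 by 1.66, 1.27 and 0.73, the 3 rises among 5 list genes with 0 falls (3 adjusted over the list alone, camera adjusted p = 0.233). The hypD call was lost without strain HR replicate 1, 2 or 3 (adjusted p = 0.0762, 0.0788 and 0.0584) and in the fit of 6 arrays (0.0806), and its change was 0.42 without strain 16 replicate 1. Strain PHC against strain HR had 4 rises, hypA, hypB, hypD and hypE by 0.96, 0.87, 0.90 and 0.70, and 0 falls (4 and 1 adjusted over the list alone, camera adjusted p = 0.233), and against strain 16 it had 0 changes among the 5. Of these rises, those of hypA and hypB were lost without any 1 of the 6 arrays but strain HR replicate 3 (adjusted p of 0.0724 to 0.1 and 0.0905 to 0.151), and that of hypE without any but strain HR replicate 1 (0.0667 to 0.12), with a change of 0.46 without strain HR replicate 3. The hypB and hypE calls were also lost after quantile normalization (0.0519 and 0.058) and with a pseudocount of 16 (0.0538 and 0.0531), and those of hypA and hypB in the fit of 6 arrays (0.0817 and 0.107), and that of hypB with the replicate number as a block (0.0739). In strain HR the array that stood apart carried the highest hypA and hypB values, with hypA at 88, 85 and 210 on replicates 1, 2 and 3. Flagellar list genes other than fliM had strain means of 25.7 to 80.3, with fliN at 65.7 ± 1.53 in strain 16 and 80.3 ± 5.69 in strain HR, while fliM was at 274, 333 and 278 in strains 16, HR and PHC. Of 21 flagellar genes 8 fell and 0 rose (4 falls adjusted over the list alone), and against strain HR strain PHC had 6 falls (3 adjusted over the list alone). Their camera adjusted p values of 0.0304 and 0.0463 became 0.071 and 0.119 without strain HR replicate 3, 0.111 and 0.11 after quantile normalization, and 0.158 and 0.135 without the dimmest probe sets, and were an adjusted p = 0.672 with an estimated correlation in both. The first was 0.0703 without strain 16 replicate 1 and the second 0.0822 without strain PHC replicate 1.

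Between strain 16 and strain HR 2408 probe sets changed, 1157 up and 1251 down, and 265 changed by at least 2-fold, 156 up and 109 down. The share of rises among all changed probe sets was 48%, and 42.1% after median centring. Named genes that changed numbered 266. Unnamed probe sets 3997 and 3998 rose by 6.76 and 5.43 on the log2 scale, and probe sets 4222 and 2182 fell, with log2 changes of -5.11 and -4.11.

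The remaining lists had no camera call in any comparison. Light harvesting and reaction centre genes had 3 rises among 7 against strain 16 and 2 against strain HR, with pufQ up by 0.52 and 0.62 in strain PHC, and 0 changes between strains 16 and HR (the same counts adjusted over the list alone). The rise of pufL against strain 16, by 0.22, was lost without strain 16 replicate 2 or 3 (adjusted p = 0.0901 and 0.0714) or strain PHC replicate 1 or 3 (0.0919 and 0.0761). Their camera adjusted p values of 0.112 and 0.0805 became 0.0375 and 0.0442 after quantile normalization, the first was 0.0496 without strain 16 replicate 1 and the second 0.0289 without strain HR replicate 3. For nitrogen assimilation, with glnA, gltB, ntrX, ureE and ureG, 1 of 5 rose in strain PHC against strain 16, 1 rose and 1 fell against strain HR, and 1 fell in strain 16 against strain HR, the same adjusted over the list alone. ATP synthase and NADH dehydrogenase genes had 2 rises and 5 falls among 13 in both comparisons of strain PHC, and 4 and 2 between strains 16 and HR, the same adjusted over the list alone. The second copy atpD Gene ID 4796502 rose in strain PHC by 1.04 and 1.49. Cytochrome and oxidase genes had 4 falls and 1 rise among 7 in strain PHC against strain 16 and 6 falls and 1 rise against strain HR, the same adjusted over the list alone, and 1 fall and 1 rise between strains 16 and HR (0 and 0 adjusted over the list alone). That fall and rise, of ccmB and ccoO, were lost without at least 4 of the 6 arrays in turn (adjusted p of 0.057 to 0.085 and 0.0987 to 0.129) and with the replicate number as a block (0.0651 and 0.0516), and that of ccoO in the fit of 6 arrays (0.0534). The rise of cycA against strain 16, by 0.15, was lost without strain 16 replicate 2 or any strain PHC array (0.0546 to 0.0968), after median centring (0.153), without the dimmest probe sets (0.0651) and with the other moderation, an intensity trend and robust prior (0.0772). Lists with under 3 measured genes were not tested, and of these gvpA, for a gas vesicle protein, was at 27.7, 27.3 and 27.7 in strains 16, HR and PHC.

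Over the 39 list tests 14 were called at the preset correlation and 0 with an estimated correlation. The latter setting did not call even the nitrogenase list in strain PHC (adjusted p = 0.178), where all 12 genes rose at least 2-fold. Its lack of calls therefore does not show that a list is unshifted.

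**Figure D2:**
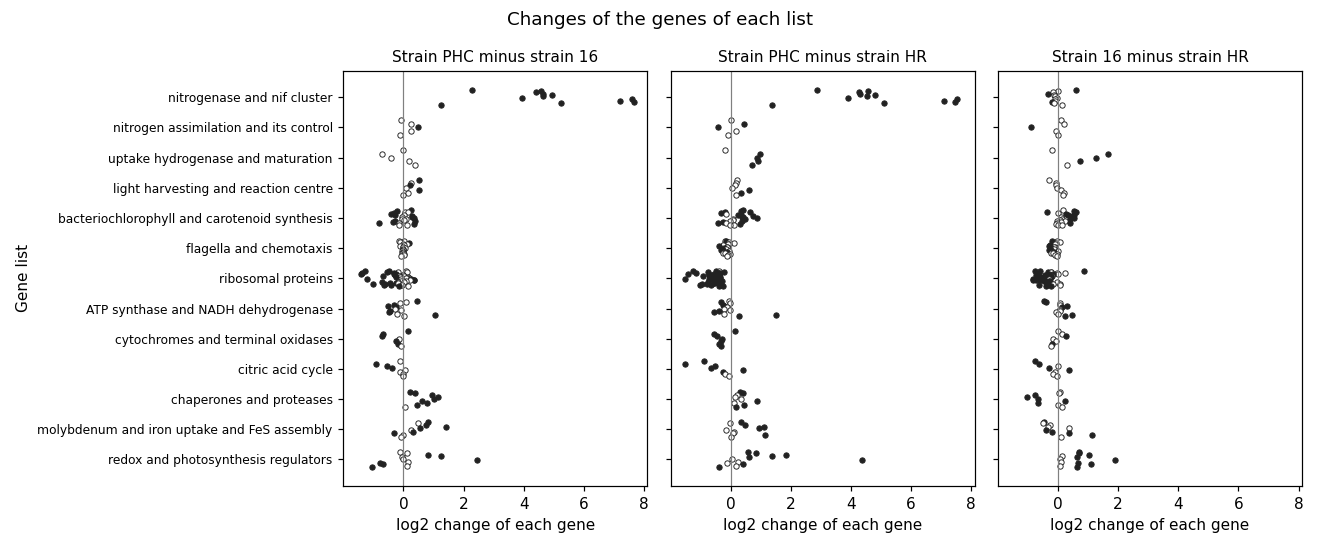
Change of each gene (log2 scale, horizontal axis) in the 13 tested lists (vertical axis), with 1 panel per comparison, 1 point per gene, and filled points for an adjusted p under 0.05. All 12 nitrogenase list genes lie right of 0 in both comparisons of strain PHC, and 44 of 45 ribosomal protein genes are filled and left of 0 for strain PHC minus strain HR.

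To see which genes set a single strain apart, probe sets that passed against both other strains with the same sign were counted. Strain PHC stood highest at 659 probe sets and lowest at 600. Of the genes named, rpoN, nifW, nifV, nifS, nifX, nifN, nifE, nifK, nifD, nifH, nifB, nifA, cbbR, exbD, dksA and atpD Gene ID 4796502 were at least 2-fold higher in strain PHC than in both others, and accB, rpmH, rpsT, rpmC and hisA at least 2-fold lower. Strain 16 had 696 higher and 488 lower, with rfbC Gene ID 3720159, moaA Gene ID 3721636 and cysE Gene ID 3721647 at least 2-fold higher and carB, dnaK, cysT and cysW at least 2-fold lower. Strain HR had 662 higher and 521 lower, and its named genes at least 2-fold lower were ppaA, cbbX, cbbR and modA. Independent lists of these sizes would share 238 and 319 probe sets for strain PHC, 276 and 259 for strain 16, and 312 and 248 for strain HR. The comparisons of a strain share its arrays. In 100 simulations with unchanged strains the mean number was 0.02, 0.01 and 0 for strains PHC, 16 and HR. Almost nothing is called when no strain differs. These means therefore do not give the overlap to compare with here, where 44.6% to 46.4% of probe sets changed in a comparison. Part of the excess over independent lists may come from the shared arrays.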

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

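The counts of changed probe sets stayed within 1.5 times of those reported under quantile normalization, median centring, removal of dim probe sets, the larger pseudocount, the fit of 6 arrays, the other moderation and array weights. At an adjusted p under 0.01 the count was 1639 for strain PHC minus strain HR and 1537 for strain 16 minus strain HR, a stricter threshold by construction. Leaving out each array in turn gave 1985 to 2278 for strain PHC minus strain 16, 2031 to 2516 for strain PHC minus strain HR and 1918 to 2384 for strain 16 minus strain HR. At least 2-fold counts were 352 to 382, 311 to 364 and 241 to 287, and strain-specific counts 1050 to 1416 for strain PHC, 935 to 1251 for strain 16 and 921 to 1242 for strain HR. Without strain HR replicate 3 the counts against strain HR were 2516 and 2384. The number of list calls, 14, was 10 to 15 with an array left out, 9 without the dimmest probe sets, 0 with an estimated correlation and 24 by fry, which does not compare a list with other genes. The cause of the change without dim probe sets was not tested. With the replicate number as a block the counts were 2287, 2470 and 2382 and the list calls 13, the citric acid cycle list being lost at an adjusted p of 0.0547. Same-numbered arrays of different strains had deviations correlated between -0.208 and 0.327 across probe sets, and 6 of 18 pairings were best with their own number, so the numbers were not taken to pair the samples. Of 210 gene results 186 kept direction and side of the threshold under every alternative run. Most of these genes were picked from the same data by the size or adjusted p of their change, which favours such stability. Among all called probe sets, at least 1961 of 2387, 2002 of 2483 and 1873 of 2408 stayed called with 1 array left out. The log2 change of glnA in strain 16 minus strain HR, not called in any setting, turned from -0.080 to 0.043 with array weights, and the cause was not tested. Signal over background may limit the calls among dim genes, which was not tested. Among the dimmest 25% of probe sets 16%, 22.8% and 20.2% were called in the 3 comparisons, against 54.1%, 54.3% and 53.3% of the others.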

Other observations

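The tests of mislabelled arrays and of consecutive numbers were chosen after the results were seen. Changed probe sets lay in runs of consecutive numbers. In strain PHC a run of 21 probe sets was at least 2-fold higher than in both other strains, from rpoN through nifA, and 12 of them are named. A further run of 13 unnamed probe sets was higher in strain PHC, by a median of 4.84 on the log2 scale against the nearer strain. In strain 16 a run of 5 followed dorR, a regulator gene of DMSO reductase expression, and ended with moaA Gene ID 3721636, with log2 differences of 3.76 to 6.76. Unnamed probe set 2182, numbered between cbbX and cbbR, was at 950 ± 131 (SD, n = 3) in strain HR and at 53.7 in both other strains, while cbbX and cbbR were lower in strain HR than in both. The 4 unnamed probe sets 2183 to 2186, numbered between 2182 and cbbR, went another way. They were lowest in strain PHC, by 1.39 to 2.33 on the log2 scale against the nearer strain. In strain 16 they were highest, by 2.42 to 3.06.

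The hydrogenase maturation gene hypD was at 1680, 954 and 821 on strain 16 replicates 1, 2 and 3, a wider spread than in strain HR, at 645, 658 and 685. The 5 probe sets of appA, fnrL and ppsR each kept 1 direction in strain 16 minus strain HR, with 5, 3 and 4 of them passing.

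Nitrogenase genes were higher in strain PHC, for nifH by 7.65 on the log2 scale against strain 16 and 7.45 against strain HR. The lowest median of the 12 list genes against strain HR was 4.48 over quantile normalization and median centring. These settings moved the median change of all probe sets by only -0.0053 and -0.074, so they could not have removed a change this large. Scale differences left between the deposited arrays are thus too small to explain it, and the authors' own normalization was not tested. A single mislabelled array would resemble another strain more than its own, and over the 5340 probe sets outside the list all 9 arrays had a lowest r with their own strain (0.991 or above) exceeding their highest r with another (0.971 or below). Exchange of the names of whole strains stays open, as does the biological candidate explanation, a genetic difference between the strains, which was not tested because the labels give no genotype.

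Ribosomal protein genes had a median log2 change of -0.52 in strain PHC minus strain HR. A brightness-dependent compression would move other probe sets of like brightness too. The 10000 random lists matched on brightness had a median of -0.018, with the central 95% of their medians between -0.19 and 0.13. Their probe sets were drawn independently, while the ribosomal list had an estimated correlation of 0.197. That range may therefore be too narrow for genes that vary together. The same bright probe set could also be drawn for several genes and in many lists, so the random lists overlap. Strain HR replicate 3 is not the source, since the median without it was -0.56. A difference in growth rate or growth stage at harvest between the strains may underlie the pattern and was not tested, and a shared preparation batch stays open.

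Neighbouring genes may change together. Of 142 consecutively numbered pairs of differently named genes, 132 (93%) are neighbours in the RefSeq table, so the numbers largely follow gene order. Pairs of consecutive probe sets that both changed at least 2-fold in 1 direction numbered 145, 133 and 85 in the 3 comparisons. In 1000 permutations there were at most 25, 21 and 18 such pairs, an excess of at least 4.72 times. Several probe sets of 1 gene stay open as an explanation for unnamed pairs. The 22 pairs with both members named were of different genes (0% of 1 gene), but 0 named genes had the probe sets to make such a pair, so this decides nothing. Shared transcripts, altered regulators and rearranged or deleted segments in a strain stay open too and were not tested.

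Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. The real split (1 of 10) gave 2387, 2483 and 2408 changed probe sets and 374, 317 and 265 at least 2-fold, and the highest of the other splits gave 0 in each. For strain-specific probe sets, 1 of 100 random splits of the 9 arrays, the real one, gave as many. The count for strain PHC was 1259 against at most 845. For strain 16 it was 1184 against at most 623, and for strain HR 1183 against at most 842. The other splits mix arrays of different strains, which widens the spread within a group. The real split was therefore likely to rank first, and its rank does not exclude chance. For the number of called lists, 14 in the real split, 43 of 100 splits gave as many and the highest gave 27, so this count cannot exclude chance. It is a weak test, since random splits hold the strains in unequal numbers and carry their differences into the list tests.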
